A study of Mus musculus with 4 samples.

How the data were processed

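Gene expression was measured in CD4+CD8+ double-positive (DP) thymocytes, the stage at which developing T cells carry both co-receptors, sorted from untreated mice of 6 to 12 weeks. Per the labels, the mice were sex-matched littermates with loxP-flanked Usp8 alleles, either without Cre (USP8ff, the control) or with Cre under Cd4 regulatory sequences (USP8ff_CD4Cre). Each of the 4 samples pooled cells from 2 mice, 8 mice in all, so that each group had 2 samples. The p-values therefore measure the spread between pools, and the number of arrays limits the precision.

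Per the labels, cRNA was made from 500 ng of RNA, labelled with Cy3 and hybridised to 1-colour Agilent arrays. Per the file headers, all 4 arrays lay on 1 slide and were read with Feature Extraction 10.7.3.1, which subtracted background and detrended each array. The deposited scanner files hold spot intensities (the processed signal, the mean signal and the local background), not normalized between arrays. The authors' deposited table of their own comparison holds an absolute fold, with its direction, and a p-value for 78 probes. The software, the test and the reference genotype behind that table are not given in the sources used here. A further deposited table of processed values has 4 columns of per-sample values whose names match no label, and it was not used.

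The log2 processed signal of each spot was set against the 75th percentile of the 43379 non-control spots of its array. Spots flagged as outliers were left out, which removed 17 of 41174 probes, and spots of a probe were averaged. A probe with several spots counted as well above background when the scanner flag held for most of them or for an equal share. Probes well above background on both arrays of at least 1 group were kept, 19038 in all (46.3%). The kept probe with the highest mean over the 4 arrays stood for its gene, giving 13062 genes, of which 4418 had several kept probes. Names came from a RefSeq table for 26690 probes by accession, and 14484 probes kept the name in the array design, which can be old. A gene whose probes carry different names is counted under each name. Probe positions are those of the scanner files, on mm9.

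Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no block), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. In 1 simulation of this comparison over 13062 genes, with 200 genes changed, 58.0% of the 2-fold, 94.7% of the 4-fold and 98.4% of the 8-fold changes were called, with 11 unchanged genes. A second simulation with no changed gene gave 0 calls. Both drew genes independently of each other. With fewer than 200 changed genes the adjustment would be stricter, so the shares called need not hold for these data. Where a probe was not well above background on either array of a group, the fold is a bound. It sets the mean of the bright group against the mean, over the dim arrays, of the higher of the probe's own value and the lowest signal well above background.

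Lists of genes were written before the data were examined. There were 29, covering ESCRT and USP8 partners, FOXO targets, TCR-induced and positive selection genes, DP-stage genes, DN-stage and beta-selection genes, mature single-positive and egress genes, NRF2 targets, ATF4 and unfolded protein response genes, p53 targets, the BCL2 family, mitotic and DNA replication genes, TCR signalling components, interferon-stimulated genes, glycolysis and hypoxia genes, cholesterol synthesis, lysosome and autophagy, endosome and receptor trafficking, proteasome, heat shock, immediate early genes, and cytokines with their receptors. The others held markers of B cells, macrophages and dendritic cells, erythroid cells, thymic stroma, granulocytes, NK, innate and gamma-delta T cells, mature regulatory and effector T cells, and sex-linked genes. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera tested on the 2 residual degrees of freedom, where few lists can pass.

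Genes were named by a rule set before the data were examined: Usp8, then the genes past the threshold with the largest differences, or, with fewer than 5 such genes, the 10 with the smallest unadjusted p and a gene symbol, and up to 2 members per list where none passed. Other genes named were chosen after their values were seen. Alternatives were quantile and median scaling, normexp background (offset 50), no filter or a filter on all 4 arrays, the mean of probes or every probe, a replicate block, an eBayes trend, a 2-fold minimum, outlier spots kept in, and each array left out in turn. Lists without Il7r were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.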

Results

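The 4 arrays, 2 per genotype, asked how loss of the deubiquitinase USP8 from the DP stage onward alters gene expression in DP thymocytes. No group carried Cre without the loxP-flanked alleles, so an effect of Cre cannot be told apart from that of the deletion. Between 18522 and 20137 probes per array (45.0% to 48.9%) were well above background, and no spot was saturated. Correlations across genes were 0.993 within USP8ff, 0.995 within USP8ff_CD4Cre and 0.991 to 0.996 between the groups, and genes are not independent replicates.

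Usp8 itself was lower in both USP8ff_CD4Cre pools. The probe well above background on all 4 arrays (mm9, chromosome 2, 126584363 to 126584422) had log2 signals of -0.23 and -0.40 in USP8ff and of -1.03 and -1.23 in USP8ff_CD4Cre, relative to the 75th percentile of each array. The log2 difference was -0.81 ± 0.13 (SE), which left 56.9% of the control signal. In limma the adjusted p was 0.60 over all genes and 0.047 adjusted over the list alone, among the ESCRT and USP8 partners. A second Usp8 probe (chromosome 2, 126559000 to 126559059) was not well above background on any array. The position of the floxed part is not given in the sources used here. A probe outside it would report the level of the transcript, not the deletion itself.

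The 10 genes with a symbol and the smallest p-values all had less signal in USP8ff_CD4Cre. Il7r, the interleukin-7 receptor alpha chain, was at least 5.01-fold lower, with log2 means of -1.95 ± 0.41 (SD) in USP8ff and -4.94 ± 0.18 in USP8ff_CD4Cre, where it was not well above background. Itgae, the integrin chain CD103, was at least 4.02-fold lower on the same basis. Nkg7, a cytotoxic granule protein gene, had a log2 difference of -2.09 ± 0.18 (SE), Cd7, a T and NK cell surface protein gene, -2.04 ± 0.16, the cyclin gene Ccnd2 -2.00 ± 0.20, and the cathepsin gene Ctss -1.96 ± 0.21. Cd7 was well above background on 1 of the 2 USP8ff_CD4Cre arrays, and with the other array set to its lowest signal well above background the difference was -1.92. Ms4a4c (-1.10 ± 0.10), Adamtsl2 (-1.02 ± 0.13) and Lypd6b (-1.01 ± 0.12) had smaller differences. Itgb3, an integrin chain, had -1.02 ± 0.10 on 1 probe, while its other kept probe had the opposite sign. All 3 kept Ccnd2 probes and both Nkg7 probes had negative differences.

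**Figure D1:**
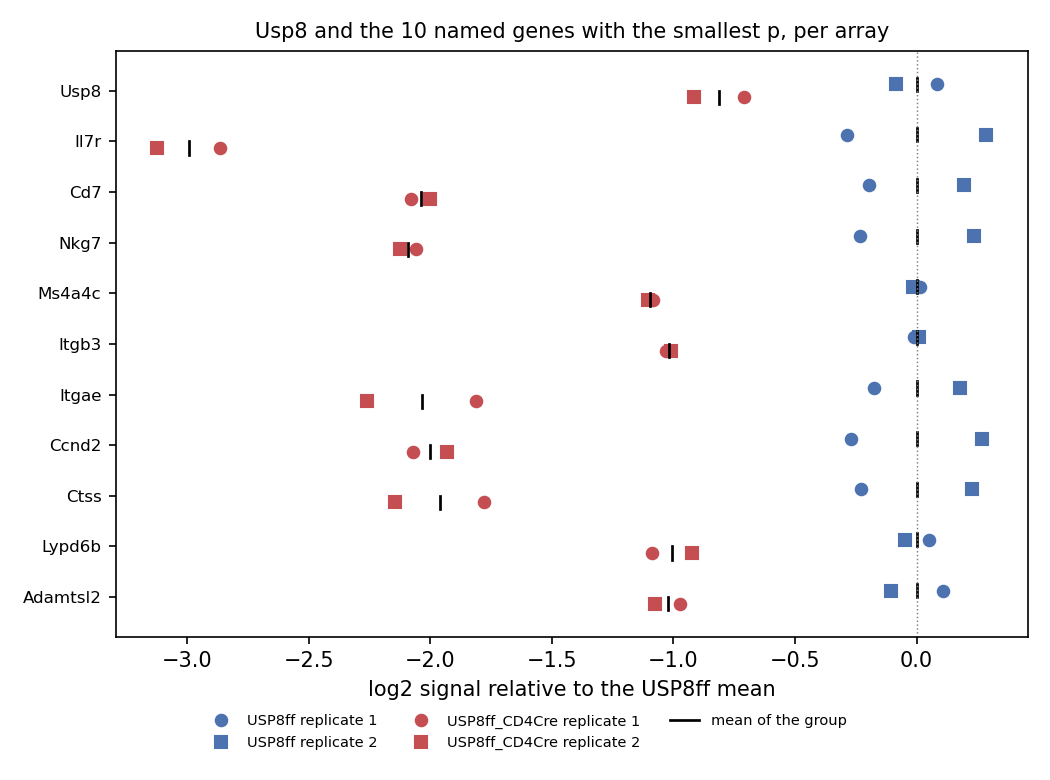
Log2 signal of each array (x axis) relative to the USP8ff mean for Usp8 and the 10 named genes with the smallest p; circles are replicate 1, squares replicate 2, blue USP8ff, red USP8ff_CD4Cre, and black bars the group means. Both USP8ff_CD4Cre arrays lie below both USP8ff arrays for each gene, with Usp8 at a mean of -0.81; Il7r and Itgae are plotted at signals that were not well above background in USP8ff_CD4Cre.

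None of these 10 genes passed adjustment: limma called 0 of 13062 genes, with a smallest adjusted p of 0.29. At an unadjusted p under 0.05 there were 518 genes higher and 452 lower in USP8ff_CD4Cre, 970 in all, where 653 would be passed by chance. That excess rested on USP8ff_CD4Cre replicate 2 and on the filter: without that array there were 396 (167 higher and 229 lower), under the 653, and with no filter on dim probes 829 of 28472, where chance gives 1424. With median scaling 337 were higher and 485 lower. Of the 970, 2 were over 2-fold higher and 39 over 2-fold lower, with each array on which a gene was not well above background set to its lowest signal well above background where that was higher. The 2, chosen after their values were seen, were Rbm45 (log2 difference 1.74 ± 0.68) and a feature with the design name NAP103733-1 (at least 2.26-fold higher). The 2 arrays of a group lay beyond both arrays of the other for 5297 genes (40.6%), against 33.3% by chance. Genes are not independent of each other, so the excess over 33.3% is not a test of the genotype.

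Mature single-positive and egress genes, which thymocytes gain after the DP stage, fell as a list (median log2 difference -0.27, camera adjusted p = 3.1e-04; adjusted p = 0.61 with an estimated correlation). Of the 22 measured members, 0 passed over all genes; adjusted over the list alone, 7 were lower and 2 higher. Beside Il7r and Itgae, and chosen after the values were seen, these were Gimap4 (at least 2.19-fold lower), the chemokine receptor gene Ccr7 (log2 difference -1.24 ± 0.23), Cd53 (-1.003 ± 0.16), Ms4a4b (-0.89 ± 0.17) and Cd52 (-0.46 ± 0.13), with Vim (0.58 ± 0.16) and Lgals1 (0.50 ± 0.11) higher. Klf2, a regulator of thymic egress, also singled out afterwards, had 0.23. Ms4a4b and Ms4a4c belong to a family of similar genes, so their signals may not be separable.

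Cytokine and cytokine receptor genes fell (25 measured, 19 with negative differences, median -0.15, adjusted p = 8.4e-06; adjusted p = 0.61 with an estimated correlation). The differences were -2.02 ± 0.34 for Il2rb, a chain of the interleukin-2 and interleukin-15 receptors that was well above background on 1 of the 2 USP8ff_CD4Cre arrays, and -0.61 ± 0.14 for Socs3, an inhibitor of cytokine signalling. Adjusted over the list alone, Il7r and Il2rb were lower. FOXO target genes fell (24 measured, median -0.07, adjusted p = 0.0079; adjusted p = 0.61 with an estimated correlation), with Il7r and Ccr7 lower when adjusted over the list alone and 22 members not passing; without USP8ff replicate 2 the adjusted p of the list was 0.19 and without USP8ff_CD4Cre replicate 2 it was 0.091. The DN-stage and beta-selection list (8 measured, median -0.09, adjusted p = 0.038; adjusted p = 0.61 with an estimated correlation) rested on Il7r: without it the adjusted p was 0.35, and it was 0.34 without USP8ff replicate 1 and 0.21 without USP8ff_CD4Cre replicate 1. Cd44, an adhesion receptor gene of that list, had -0.76 ± 0.31. Its log2 signals were -0.79 and -1.72 in replicates 1 and 2 of USP8ff, and -1.93 and -2.11 in those of USP8ff_CD4Cre.

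Markers of other cells moved with these groups. Macrophage and dendritic cell markers fell (13 measured, median -0.12, adjusted p = 0.018; adjusted p = 0.61 with an estimated correlation), with Ctss and Mpeg1 (-1.09 ± 0.23) lower when adjusted over the list alone. NK, innate and gamma-delta T cell markers fell (7 measured, median -0.13, adjusted p = 0.018; adjusted p = 0.61 with an estimated correlation), with Nkg7, Il2rb and, chosen afterwards, the perforin gene Prf1 (-0.86 ± 0.21) lower on that basis. The granzyme gene Gzma (0.42 ± 0.20) and Tbx21 (0.15 ± 0.10), a transcription factor gene of NK and T cells, also chosen afterwards, had positive differences and did not pass. Regulatory and effector T cell markers fell (7 measured, median -0.20, adjusted p = 0.018; adjusted p = 0.61 with an estimated correlation), with Gpr83 (-1.94 ± 0.30, well above background on 1 of the 2 USP8ff_CD4Cre arrays) lower and Icos, a co-stimulatory receptor gene, at -0.59 ± 0.18. Of the 7 regulatory and effector members, 2 had positive differences, Ikzf2 (0.23) among them. The calls of these 3 marker lists were also each lost with 1 array left out. The adjusted p of the macrophage list was 0.058 without USP8ff replicate 1 and 0.069 without USP8ff_CD4Cre replicate 1. That of the NK list was 0.13 without USP8ff_CD4Cre replicate 1 and 0.088 without USP8ff replicate 2. That of the regulatory T cell list was 0.077 without USP8ff replicate 1 and 0.0503 without USP8ff_CD4Cre replicate 2. B cell (5 measured, median -0.08, adjusted p = 0.75), erythroid (3 measured, 0.31, adjusted p = 0.75) and thymic stroma markers (7 measured, -0.10, adjusted p = 0.36) did not pass. Their members with the smallest p had log2 differences of -0.75 (Blnk) and 0.53 (Igh-6), of -0.30 (Car1) and 0.81 (Hba-a2), and of -0.47 (Epcam) and 0.22 (Krt5, well above background on 1 of the 2 USP8ff arrays). Of the granulocyte markers 1 was measured, and that list was not tested.

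Interferon-stimulated genes fell: 23 of 28 measured members had negative differences, with a median of -0.23 (adjusted p = 8.4e-06; adjusted p = 0.61 with an estimated correlation). Ifit3 had -0.81 ± 0.18. Oasl2, of the oligoadenylate synthetase family, had -1.29 ± 0.36, but it was well above background on 1 of the 2 USP8ff_CD4Cre arrays, and with the other array set to its lowest signal well above background the difference was -0.79. Of the list, 0 members passed over all genes or when adjusted over the list alone. The mean of the list relative to the 4 arrays was -0.28 in replicate 1 and -0.0025 in replicate 2 of USP8ff_CD4Cre, and without USP8ff_CD4Cre replicate 1 the mean difference went from -0.28 to -0.14, with the call kept (adjusted p = 0.017).

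Mitotic and DNA replication genes rose: all 32 measured members had positive differences, with a median of 0.49 (adjusted p = 9.4e-16; adjusted p = 0.61 with an estimated correlation, which was 0.85). The proliferation marker gene Mki67 had 0.52 ± 0.15 and Tyms, which makes thymidylate, 0.52 ± 0.14. Adjusted over the list alone, 0 members passed. The mean of the list relative to the 4 arrays was 0.05 in replicate 1 and 0.41 in replicate 2 of USP8ff_CD4Cre, and -0.13 in replicate 1 and -0.33 in replicate 2 of USP8ff, and without USP8ff_CD4Cre replicate 2 the mean difference went from 0.46 to 0.28.

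**Figure D2:**
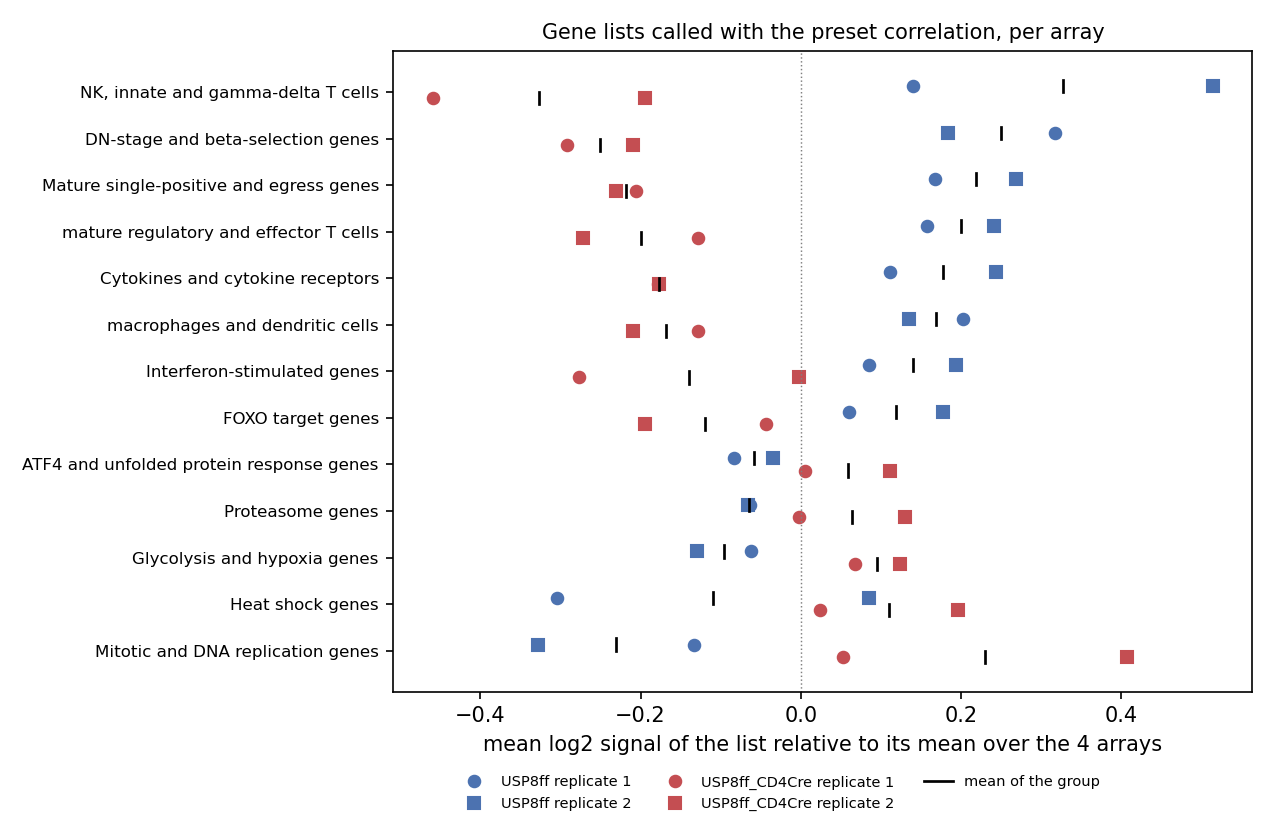
Mean log2 signal of each called gene list per array (x axis), relative to the list's mean over the 4 arrays; circles are replicate 1, squares replicate 2, blue USP8ff, red USP8ff_CD4Cre, and black bars the group means. Mitotic genes had the largest mean rise of the 13 lists shown (0.46 between the groups), and heat shock genes overlapped between the groups.

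Glycolysis and hypoxia genes rose (21 of 25 positive, median 0.20, adjusted p = 8.7e-04; adjusted p = 0.61 with an estimated correlation), with Ndrg1 at 0.57 ± 0.14 and the growth factor gene Vegfa at 0.57 ± 0.15. Proteasome genes rose (33 of 36 positive, median 0.12, adjusted p = 3.3e-04; adjusted p = 0.63 with an estimated correlation), with the subunit genes Psmb3 at 0.27 ± 0.10 and Psmd7 at 0.26 ± 0.10. Heat shock genes rose (15 of 16 positive, median 0.24, adjusted p = 0.016; adjusted p = 0.61 with an estimated correlation), with the mitochondrial chaperone gene Hspa9 at 0.38 ± 0.11 and Bag3 at 0.37 ± 0.15; without USP8ff replicate 1 the mean difference went from 0.22 to 0.025 and the adjusted p was 0.80, and without USP8ff replicate 2 the mean was 0.41. ATF4 and unfolded protein response genes rose (21 of 26 positive, median 0.11, adjusted p = 0.038; adjusted p = 0.61 with an estimated correlation), with the one-carbon enzyme gene Mthfd2 at 0.63 ± 0.16 and the serine synthesis gene Psat1 at 0.54 ± 0.15. Without USP8ff_CD4Cre replicate 2 the mean difference went from 0.13 to 0.063 for proteasome, from 0.22 to 0.13 for heat shock and from 0.12 to 0.064 for ATF4 genes, and the adjusted p was 0.22, 0.17 and 0.38. Without USP8ff_CD4Cre replicate 1 the proteasome mean was 0.195, and without USP8ff replicate 1 the adjusted p of ATF4 genes was 0.29. In none of these 4 lists did a member pass over all genes or when adjusted over the list alone.

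The other lists did not pass. ESCRT and USP8 partners had a median of 0.02 over 31 measured members and a mean of -0.01 (adjusted p = 0.74), with the ESCRT-II gene Vps36 at 0.21 ± 0.11. DP-stage genes had a median of -0.06 (29 measured, 21 negative, adjusted p = 0.13), with the recombination gene Rag2 at -0.33 ± 0.13 and the antigen-presenting molecule gene Cd1d1 at -0.25 ± 0.12; with quantile normalization this list passed (adjusted p = 6.1e-04). TCR signalling components had -0.01 (36 measured, adjusted p = 0.14; adjusted p = 0.0074 with quantile normalization), with the phosphatase gene Ubash3b at -0.62 ± 0.14 and the kinase gene Fyn at -0.29 ± 0.12. TCR-induced and positive selection genes had -0.02 (25 measured, adjusted p = 0.47), with Ikzf2 at 0.23 and Nab2 at -0.33. The BCL2 family had a median of -0.02 (15 measured, adjusted p = 0.73), with the pro-apoptotic genes Bmf at -0.94 ± 0.26 and Pmaip1 at 0.84 ± 0.50. The log2 signals of Bmf were 3.92 and 4.66 in USP8ff, and 3.28 and 3.43 in USP8ff_CD4Cre. Those of Pmaip1 were -1.51 and -0.38 in USP8ff, and -0.66 and 0.45 in USP8ff_CD4Cre. p53 targets had a median of 0.05 (17 measured, adjusted p = 0.75), with Rrm2b at -0.34 and Ckap2 at 0.40. NRF2 targets had 0.07 (24 measured, adjusted p = 0.23), with the glutathione genes Gclm and Gsr both at 0.36.

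Cholesterol synthesis genes had a median of 0.10 (31 measured, adjusted p = 0.18), with Tmem97 at 0.68 and Idi1 at 0.33. The mean difference of this list went from 0.10 to 0.24 without USP8ff replicate 1 and to -0.04 without USP8ff replicate 2. Lysosome and autophagy genes had a median of -0.03 (34 measured, adjusted p = 0.23), with Map1lc3a at 0.27 and Naglu at -0.38. Endosome and receptor trafficking genes had 0.06 (28 measured, adjusted p = 0.22), with Snx27 at 0.30 and Ehd4 at 0.31. Immediate early genes had a median of -0.01 and a mean of 0.04 (18 measured, adjusted p = 0.75). With the filter on all 4 arrays, which left out Fosl2, the mean was -0.036. Socs3 belongs to this list too, and Fosl2 was well above background in USP8ff_CD4Cre only, at a level too low for a fold. As a check of the labels, the sex-linked list had a median of -0.20 (4 measured, adjusted p = 0.14), with Eif2s3y at -0.28 and Kdm5d at -0.25, and no Xist probe was well above background on any array. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on all 4 arrays. Signal of these genes without Xist is that of male mice in every pool, as the sex-matched label requires.

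Of the 28 lists tested, 13 passed with the preset correlation, 5 higher and 8 lower, 0 with an estimated correlation and 1, the macrophage and dendritic cell markers, with fry. The 0 with an estimated correlation cannot be laid to correlated members alone, as that test had 2 residual degrees of freedom. The estimate was 0.85 for mitotic, 0.48 for proteasome, 0.28 for interferon-stimulated and 0.27 for FOXO genes. NK markers had 0.27, heat shock genes 0.20 and ATF4 genes 0.12. For these lists, far above the preset 0.01, the preset p-values may be too small. Estimates were lower for glycolysis (0.061), cytokine (0.039), regulatory T cell (0.0305) and DN-stage genes (0.020), and negative for macrophage markers (-0.080). For the mature single-positive list the estimate was 0.0127, near the preset 0.01. Before adjustment its camera p went from 4.5e-05 to 0.057. The calls of 5 lists held under every other setting run, those of mature single-positive, mitotic, interferon-stimulated, glycolysis and cytokine genes, and 8 lists lost theirs under at least 1. The sizes held less well. Beside the arrays left out, these settings moved the mean difference of a called list by over 1.5 times. With the filter on all 4 arrays it went from -0.44 to -0.19 for mature single-positive genes (adjusted p = 0.041), from -0.35 to -0.18 for cytokine genes, from -0.24 to -0.13 for FOXO targets, from -0.50 to -0.14 for DN-stage genes, from -0.65 to -0.43 for NK markers and from -0.40 to -0.14 for regulatory T cell markers. With normexp the means of these 6 lists were -0.24, -0.23, -0.16, -0.22, -0.32 and -0.24, while that of interferon-stimulated genes went from -0.28 to -0.18 and that of macrophage markers from -0.34 to -0.21. Without Il7r the mean was -0.12 for FOXO targets (adjusted p = 0.036) and -0.14 for DN-stage genes. With no filter it was -0.31 for DN-stage genes and went from 0.12 to 0.077 for ATF4 genes, and with quantile normalization it went from 0.13 to 0.065 for proteasome genes.

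The authors' deposited table lists 78 probes, 2 of them array controls, 25 of the rest marked up and 51 down. The 2 controls, AT_nX_3 (446.9-fold up) and AT_nX_5 (168.8-fold up), had its largest folds. All 76 gene probes differed here in the marked direction if up means higher in USP8ff_CD4Cre, and 27 passed the filter on dim probes. Limma called 0 of the 20 that stood for a gene, while all 27 had an unadjusted p under 0.05. In the authors' deposited table Il7r was 7.94-fold down and its p was 0.011. Both comparisons come from the same arrays and are not independent.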

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

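The tests on the control spots and on the markers of other cells were chosen after the results were seen; the 3 tests on mitotic genes were written down before their results. Control spots are outside the gene comparison, and 6 of the 38 control probes well above background on both USP8ff_CD4Cre arrays lay higher there than in both USP8ff arrays by more than the range within a group. AT_nX_3 was at least 129.3-fold and AT_nX_5 at least 40.8-fold higher. The log2 difference was 0.55 for AT_ssM_RR_3, 0.32 for (+)eQC-39, 0.16 for AT_ssM_AB_3 and 0.16 for DCP_22_7. The scaling to the 75th percentile accounts for part of this: the median over the 35 control probes well above background on all 4 arrays was 0.16 with it and 0.05 without it. Without it, 3 of the 6 stood out on the same basis, both AT_nX probes and AT_ssM_RR_3 (0.43), while (+)eQC-39 (0.20), AT_ssM_AB_3 (0.05) and DCP_22_7 (0.04) did not.

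The AT_nX signal was absent from USP8ff, with 0 of 16 spots well above background. A spike-in mix that also holds the AT_nB, AT_nC and AT_nD targets would raise those probes too, and their largest absolute log2 difference was 0.36. A local defect of the slide would spare some spots, and 16 of 16 were well above background in USP8ff_CD4Cre. The 4 letters run parallel to the bioB, bioC, bioD and cre controls of another array maker, so a candidate explanation is RNA of the Cre transgene, seen on 2 of the 2 USP8ff_CD4Cre arrays. The target of these spots is not given in the sources used here, and an RNA added to those samples alone cannot be told apart from it.

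The lower signal of mature T cell genes may reflect fewer mature single-positive cells in the sort, or a change within DP cells. The median of the 22 mature single-positive members was -0.27, with a spread of 0.87 over members, which decides neither: Il7r and Itgae were far lower while Vim and Lgals1 were higher. Of these 22, 5 are also in another list, and the sort for CD4 and CD8 would remove most single-positive cells. Fewer macrophages and dendritic cells in the sort stay open as well, although the sort would remove most of these too: 10 of their 13 members had negative differences, with a median of -0.12 and a spread of 0.61, Cd74 and H2-Eb1 at -0.45 and Apoe at -0.59, but Lyz2 at -0.19 and C1qb, well above background on 1 of the 2 USP8ff arrays, at 0.25. The genotype stays open as a cause of each.

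The rise of mitotic genes was not removed by the scaling between arrays, since the smaller mean difference under quantile normalization and median scaling was 0.40. A trend with signal level is argued against by its median, at percentile 100 of 10000 random lists matched on level. The medians of the macrophage (percentile 7.14), NK (9.92) and DN-stage lists (13.1) were not apart from such lists. The small rises of the proteasome (98.1) and ATF4 lists (98.2) stood little beyond them. The DP-stage list, which did not pass camera, was at percentile 0.01. Cholesterol (98.6), erythroid (97.8), TCR signalling (2.59), lysosome (2.36) and sex-linked genes (2.17), which did not pass camera either, also lay near an end. The random lists were matched on level alone and do not keep the correlation between members. A percentile near an end therefore does not show a shift by genotype. If a single deviating array made the whole rise of mitotic genes, leaving it out would end the rise. The smallest mean difference with 1 array left out was 0.28, without USP8ff_CD4Cre replicate 2, against 0.46 with all arrays. That 1 array enlarged the rise stays open. Pools that differ in their share of cycling cells by chance stay open, since with an estimated correlation the p was 0.21 before adjustment, as does the genotype.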

How the results depend on the processing

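Lists without Il7r were added after the data were seen. The count of genes past the threshold in limma was 0 higher and 0 lower under every setting run, with 167 to 660 genes higher and 229 to 697 lower at an unadjusted p under 0.05; the fewest in both directions came without USP8ff_CD4Cre replicate 2. The Usp8 difference stayed negative throughout, from -0.92 to -0.66, and never passed. All 76 gene probes of the authors' deposited table kept their direction under the scalings, normexp, outlier spots kept in and each array left out. That table comes from the same arrays and holds only probes with large folds and small p-values between the groups. Their kept direction was therefore largely fixed beforehand and adds no support. For the 57 other named genes, 788 of 790 recomputed values kept their direction and side of the threshold. With 0 genes called under every setting, none could change side. Most of these genes also had both arrays of a group beyond those of the other, where leaving out 1 array cannot turn the direction. The count was thus largely fixed beforehand and adds no support. Itgb3 had 0.0195 with normexp, where its other probe became the brighter, and Hba-a2 ranged from -0.0018 (without USP8ff_CD4Cre replicate 2) to 1.63 with 1 array left out. With the filter on all 4 arrays, 8 named genes had no value. Without the filter, the median of all genes moved to -0.13. Low signal over background limits genes near the floor. The replicate number as a block (replicate block) gave 0 calls, 641 genes higher and 697 lower at an unadjusted p under 0.05. The smallest adjusted p in limma was 0.091 with the block, against 0.29 without it. Same-numbered deviations correlated at 0.32, and 2 pairs cannot show whether the arrays were paired. The authors' processed values were not run, since their columns match no label, nor the slide as a block, with 1 slide. For the changes below the cause was not tested unless named.

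With an estimated correlation 0 lists passed; the adjusted p was 0.63 for the proteasome list and 0.61 for the other 12 called lists. With fry 1 passed; the adjusted p was 0.48 for FOXO, 0.36 for DN-stage, 0.299 for mature single-positive, 0.42 for ATF4, mitotic, interferon-stimulated, proteasome and NK genes, 0.31 for glycolysis and cytokines, 0.54 for heat shock and 0.34 for regulatory T cell genes. Without Il7r, DN-stage genes had 0.35. With quantile normalization DP-stage (6.1e-04) and TCR signalling genes (0.0074) passed as lower, while DN-stage (0.071), ATF4 (0.083), proteasome (0.052) and macrophage genes (0.073) lost their calls. With normexp DN-stage, ATF4 and macrophage genes lost theirs (each 0.074), and camera's direction turned to higher for the BCL2 family (0.92). With no filter p53 (0.022), cholesterol (0.0024) and endosome genes (0.0068) passed as higher, macrophage genes lost their call (0.063), and camera's direction turned to higher, without passing, for ESCRT (0.37), DP-stage (0.94), BCL2 (0.65), TCR signalling (0.76), lysosome and immediate early (each 0.62) and stroma genes (0.96). Camera sets a list against all other genes, whose median had moved to -0.13: the list means stayed negative for ESCRT, DP-stage, TCR signalling, lysosome and stroma genes. With the filter on all 4 arrays, which removes Il7r, DN-stage genes had 0.33, and NK and regulatory T cell genes 0.15. With the mean of probes DP-stage genes passed (0.024), ATF4 genes did not (0.078), and camera's direction turned to higher for immediate early genes (0.96).

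With 1 array left out, its group was assumed to vary like the other, and 8 (without USP8ff_CD4Cre replicate 2) to 11 lists passed. The adjusted p ranged from 9.6e-04 to 0.19 for FOXO (lost without either replicate 2), 0.0013 to 0.34 for DN-stage (lost without either replicate 1), 0.014 to 0.38 for ATF4 and 1.3e-05 to 0.80 for heat shock (both lost without USP8ff replicate 1 or USP8ff_CD4Cre replicate 2), 1.5e-04 to 0.22 for proteasome (lost without USP8ff_CD4Cre replicate 2), 0.0032 to 0.069 for macrophage (lost without either replicate 1), 1.7e-04 to 0.13 for NK (lost without USP8ff_CD4Cre replicate 1 or USP8ff replicate 2) and 0.0082 to 0.077 for regulatory T cell genes (lost without USP8ff replicate 1 or USP8ff_CD4Cre replicate 2). Without USP8ff replicate 1, DP-stage (0.039 to 0.66), TCR signalling (0.023 to 0.92) and cholesterol genes (3.8e-04 to 0.47) passed. Camera's direction turned, without passing, for cholesterol genes, TCR-induced (0.095 to 0.64), p53 (0.075 to 0.88), BCL2 (0.22 to 0.97), immediate early (0.39 to 0.72), B cell (0.28 to 0.88) and erythroid genes (0.0795 to 0.87).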

Other observations

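The test here was chosen after the data were seen. Histone genes, picked by name, had mostly higher signal in USP8ff_CD4Cre: 25 of 30 had positive differences, with a median of 0.41, or 0.25 with quantile normalization and 0.40 with median scaling. H2ac4 had a log2 difference of 0.71 and H4c6 of 0.56, while H1f0 had -0.57. Camera with the preset correlation gave p = 2.8e-08, against p = 0.23 with an estimated correlation. More DNA-replicating cells would raise histone genes, but this set was chosen after such genes were seen to be higher, so its rise does not test that hypothesis, which stays open. Histone genes have near-identical copies, so single members are uncertain, and the arrays are those of the mitotic list.

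Of the 39 genes over 2-fold lower at an unadjusted p under 0.05, with each array on which a gene was not well above background set to its lowest signal well above background where that was higher, 11 belong to a list written beforehand. The others include, singled out after their values were seen and given as log2 differences, Xlr3c (-1.76), Esrp2 (-1.54), Hrh3 (-1.48) and Arap3 (-1.31). Xlr3c has close copies on the array. None of these passed adjustment in limma. Genes were counted by name, so a gene whose probes carry different names can be counted more than 1 time among the 39.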
